A study of Homo sapiens with 18 samples.

How the data were processed

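RNA sequencing was done on 4 human glioblastoma cell lines, A172, LN18, T98G and U87MG, each as cells sensitive and cells resistant to TRAIL, the death ligand encoded by TNFSF10. The 18 libraries fall into 9 groups of 2, taken from the sample titles: sensitive and resistant A172, LN18 and T98G cells, and sensitive, R50 and R250 U87MG cells. The labels do not say what the numbers in R50 and R250 stand for. Per the labels, cells of passages 22 to 25 were grown for 24 h in medium with 10% serum. Part of the sample descriptions and file columns name the sensitive A172 cells A171, and these were taken as A172 from the titles. Nothing in the labels says that the 2 libraries of a group come from separate cultures, so the p-values measure only the spread between these samples.

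The deposited values are counts, whole numbers of reads per gene from featureCounts with no normalization, in 57820 rows with 1 column per library. The authors list HISAT2 2.1.0, DESeq2 1.20.0 and genome build hg19; the annotation release, strand setting, handling of reads that map to several places and library kit are not stated. Genes carry the symbols of the deposited table, some of which are older names (IL8 for CXCL8, PRKCDBP for CAVIN3, WISP2 for CCN5). No coordinates are given, since no annotation of that build was at hand. Reads shared between close relatives, such as CXCL1, CXCL2 and CXCL3 or ribosomal protein genes and their pseudogenes, cannot be separated in a table of counts.

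Totals ran from 19.1 to 20.3 M reads per library in A172, LN18 and T98G and from 37.1 to 44.6 M in U87MG, so line and depth go together. The 10 most abundant genes took at most 9.39% of a library. Within every group the 2 libraries differed by more than counting error, with chi-square per degree of freedom from 1.58 to 12.2, and their correlation across genes was 0.99 or more. Floors and counting intervals below cover counting error only.

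The tests and their thresholds, the gene lists and the rule for naming genes were set before the data were examined. Counts were scaled by TMM and tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3 (limma 3.58.1), two-sided, with 1 mean for each of the 9 groups, so that all groups share an estimate of the spread. The filter filterByExpr left 19784 genes, which hold at least 99.9% of the reads of every library. A call is a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. Levels are TMM-scaled counts per M reads (CPM), given as mean ± SD over the 2 libraries of a group, and log2 fold changes as estimate ± SE. The 6 comparisons are resistant with sensitive cells in each line, with R50 and R250 taken apart, and R250 with R50. The change shared by the lines was tested on 8 sums of counts, 1 per line and condition, with line as a term, and an F-test over the 18 libraries asked whether the change is equal in the 4 lines. Against a group with 0 reads a fold is a lower bound, computed as if the group held 3 reads over its 2 libraries; against a group with 1 to 3 reads the ratio is given with an exact 95% binomial interval.

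Genes named are the 8 largest increases and 8 largest decreases among calls with a mean of at least 5 CPM in the higher group and no overlap between the libraries of the 2 groups (5 and 5 for R250 with R50), all members of the list of TRAIL receptors and death-inducing complex, up to 4 members of each other list with the smallest adjusted p, and the 10 genes each way with the smallest p for the shared change; some of these are left out, and genes outside the rule are said to be so. The 26 lists were tested with camera at a preset correlation of 0.01, adjusted over 182 tests (26 lists in 6 comparisons and the shared change), with an estimated correlation and fry beside it. fry asks whether the genes of a list move one way on balance and does not compare the list with other genes. Cell line identity was described with the Pearson correlation of log2 CPM across genes.

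On simulated counts with the libraries' depths, 50 genes changed 2-fold were recovered at 62% in A172, 68% in LN18, 62% in T98G, 64% in R50 and 62% in R250, each among 19784 genes. Of the unchanged genes, 0.0511% were called in LN18. Far fewer genes were changed in the simulation than were called in the real comparisons with sensitive cells, so these rates need not hold there. For the shared change 88% of changed and 0.174% of unchanged genes were called, but these counts were simulated without a spread between the lines, so the values do not describe the real test.

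The alternatives were DESeq2 size factors or library totals in place of TMM, no filter or a filter of 1 CPM in 2 libraries, the DESeq2 test, a fit to the libraries of a comparison alone, a replicate block, a minimum fold of 1.5 and leaving out each library. For the shared change they also took R50 or R250 alone, left out each line, and used the single libraries. Leaving out the A172 libraries in the other comparisons, thinning every library to 19105151 reads, and leaving out libraries for the shared change, the overlaps, the lists and the identity were chosen after seeing the data. Where leaving out a library leaves a group with 1, that library is taken to vary like the other groups.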

Results

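The series sets glioblastoma cells that resist TRAIL beside the sensitive cells of the same line. TRAIL kills cells through the receptors DR4 (TNFRSF10A) and DR5 (TNFRSF10B), which recruit FADD and caspase 8 (CASP8), while TNFRSF10C, TNFRSF10D and the secreted TNFRSF11B bind it without signalling death. Each of 9 groups has 2 libraries: sensitive and resistant cells of A172, LN18 and T98G, and sensitive, R50 and R250 cells of U87MG. Depth was about 20.2 M reads per library in sensitive and 19.7 M in resistant A172 cells, 20.2 and 19.1 M in LN18, 20.1 and 19.5 M in T98G, and 38.7, 43.4 and 40.7 M in sensitive, R50 and R250 U87MG cells.

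The first question was whether each resistant group carries the profile of its labelled line. Resistant LN18 and T98G libraries correlated across genes with their own sensitive cells at a mean r of 0.964 and 0.953, and U87MG R50 and R250 at 0.99 and 0.988. The 2 libraries labelled A172 resistant correlated at 0.832 with sensitive A172 and at 0.936 with sensitive U87MG cells, so 8 of the 10 resistant libraries were closest to their own line. Genes are not independent replicates, and no test is attached to these correlations. A set of 18 genes was at 10 CPM or more in sensitive A172 and under 0.2 CPM in the sensitive cells of the other lines; 0 of them reached 1 CPM in the libraries labelled A172 resistant. Of 27 genes restricted in that way to U87MG, 26 reached 1 CPM there, summing to 1288 CPM against 1558 CPM in sensitive U87MG cells, and of 20 LN18 genes 6 did, at 3.72% of their sum in LN18. Resistant LN18 cells kept 20 of 20 LN18 genes and resistant T98G cells 3 of 3 T98G genes at that level. The A172 comparison is therefore given apart from the others, and shared genes and overlaps are given with and without it.

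**Figure D1:**
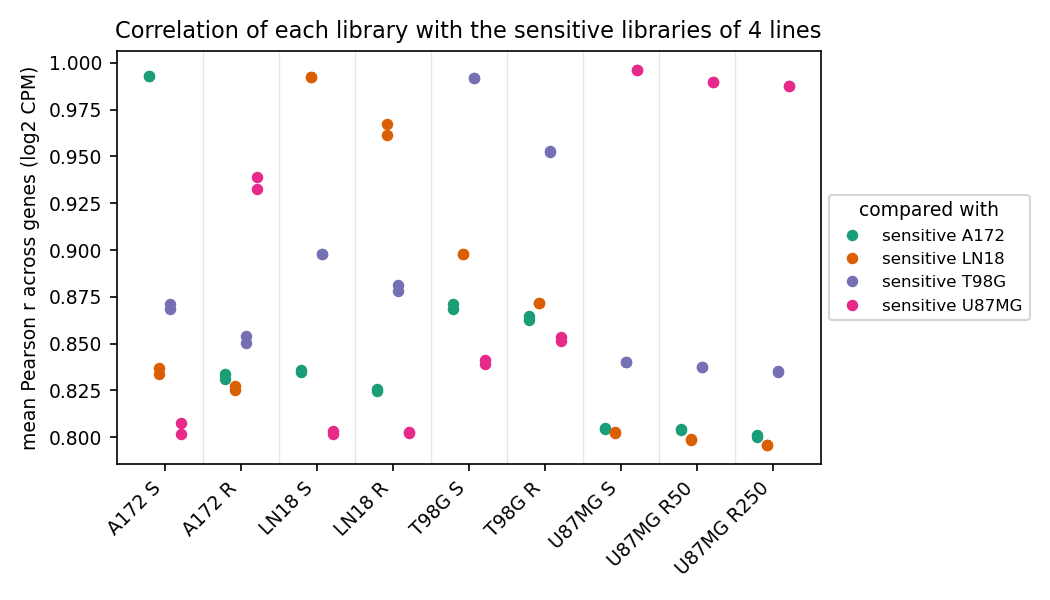
Mean Pearson correlation across genes (log2 CPM, vertical axis) of each library, by group on the horizontal axis, with the sensitive libraries of 4 lines (colours); each point is 1 library. The libraries labelled A172 resistant lie at 0.936 with sensitive U87MG and 0.832 with sensitive A172 cells.

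In LN18 the comparison asks what separates resistant from sensitive cells of that line. The BMP antagonist CHRDL1 rose from 1.45 ± 0.0686 to 52.2 ± 3.89 CPM (log2 fold change 5.17 ± 0.14, adjusted p = 2.43e-23, n = 2 each, edgeR). The proteoglycan SPOCK1 rose by 4.97 on the log2 scale to 54.6 ± 0.736 CPM, the adhesion molecules NCAM1 and CADM1 by 4.20 and 4.16, and the receptor FGFR2 by 4.38. The TNF-family ligand TNFSF18 fell from 30.5 ± 0.371 to 0.865 ± 0.682 CPM (log2 -5.13 ± 0.21, edgeR adjusted p = 7.97e-18), and CD96, the histone deacetylase HDAC9 and the repair gene XRCC2 changed by -4.31, -3.63 and -3.48. In all, edgeR called 10798 genes, 5156 higher and 5642 lower, of which 3768 changed at least 2-fold and 4071 passed a test against a 1.5-fold change.

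The death-receptor machinery was lower in resistant LN18 cells at several points. DR4 (TNFRSF10A) fell from 33.5 ± 1.54 to 4.32 ± 0.317 CPM (log2 -2.95 ± 0.16, adjusted p = 1.53e-15, edgeR) while DR5 (TNFRSF10B) was at 178 ± 1.64 and 162 ± 12.6 CPM and not called (adjusted p = 0.0775). The kinase RIPK1 fell by 2.04 ± 0.10 on the log2 scale, FADD by 0.94 ± 0.20, CASP8 by 0.69 ± 0.10 and the decoy TNFRSF10C by 1.40 ± 0.20. TNFRSF11B and TNFRSF1A rose by 0.62 and 0.36, and FAS and CASP10 changed by -0.38 and -0.45. No call was made by edgeR for TNFSF10 (log2 -0.18), TNFRSF10D (-0.18), the caspase 8 inhibitor CFLAR (0.11) or TRADD (-0.14), so 2 of the 14 measured members were higher and 7 lower (2 and 8 adjusted over the list alone). The list was called lower by camera at adjusted p = 0.043, but at 0.524 with an estimated correlation. That call was lost with the replicate block (camera adjusted p = 0.0905). It was also lost without sensitive replicate 1 (median log2 -0.26) and without resistant replicate 1 (-0.38). FAS lost its call without sensitive replicate 1 (adjusted p = 0.0502) or resistant replicate 2 (0.107), and CASP10 without sensitive replicate 1 (0.213), resistant replicate 1 (0.098) or resistant replicate 2 (0.0782), with DESeq2 (0.089) and in the fit to the libraries of the comparison alone (0.0537). TNFRSF10B was called lower with library totals (adjusted p = 0.00276), the replicate block (0.0428) and without resistant replicate 2 (0.0127), and TNFRSF10D with library totals (0.00339), no filter (0.0389), the block (0.012) and without resistant replicate 2 (0.00207). Over every alternative with a test of any change the adjusted p ran from 2.54e-04 to 0.107 for FAS, 0.00884 to 0.213 for CASP10, 0.00276 to 0.635 for TNFRSF10B and 0.00207 to 0.695 for TNFRSF10D.

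Further down the pathway, the BH3-only gene HRK fell from 2.92 ± 0.65 to 0.272 ± 0.00303 CPM, and cytochrome c (CYCS) fell by 0.55 on the log2 scale. The pore former BAK1 rose by 1.13. Among inhibitors of death BCL2 fell by 1.66, whereas BCL2L1 rose by 0.67 and survivin (BIRC5) by 1.33. BIRC5 is also counted in the list of G2/M genes, most of which rose in these cells. Of the 19 measured pro-apoptotic genes and caspases 5 were higher and 13 lower, and of 14 anti-apoptotic genes 4 and 6 (over all genes; 5 and 6 adjusted over the list alone, with the pro-apoptotic counts unchanged). Neither list was called by camera.

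NF-kB targets and cytokines were lower in resistant LN18 cells. The adhesion receptor ICAM1 fell from 119 ± 4.12 to 24.6 ± 1.96 CPM (log2 -2.28 ± 0.090, adjusted p = 9.87e-19, edgeR), IL1B from 26.3 ± 3.01 to 4.94 ± 0.713 CPM, and the NF-kB inhibitor TNFAIP3 by 1.09 on the log2 scale. Of 31 measured members 25 were lower and 1 higher (the same counts adjusted over the list alone), with a median log2 fold change of -1.09 (camera adjusted p = 3.58e-10, and 0.328 with an estimated correlation). Cell-cycle genes parted by phase: the mitotic kinesin KIF20A rose from 33.7 ± 6.59 to 189 ± 4.69 CPM, cyclin B1 (CCNB1) by 2.61 and PLK1 by 1.81 on the log2 scale, and 28 of 32 G2/M genes were higher and 0 lower (29 and 0 adjusted over the list alone), with a median of 1.09. The replication genes MCM3, MCM6 and UHRF1 fell by 1.44, 1.46 and 1.89, and 25 of 32 G1/S genes were lower and 0 higher, over all genes and over the list alone, with a median of -0.96 (camera adjusted p = 4.77e-20 and 4.82e-11, but 0.287 and 0.600 with an estimated correlation).

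Ribosomal, glycolytic and matrix genes were higher in resistant LN18 cells. RPL4 rose by 1.37 ± 0.069 on the log2 scale, and 38 of 39 ribosomal protein genes were higher (median 0.83; the same count adjusted over the list alone). The hypoxia gene CA9 rose from 7.73 ± 1.16 to 57.7 ± 9.44 CPM and NDRG1 by 1.56, with 26 of 31 members of the hypoxia and glycolysis list higher and 2 lower (median 0.75, counts unchanged over the list alone). Vimentin (VIM), fibronectin (FN1), TGFBI and SPARC rose by 1.47, 1.48, 1.29 and 1.66, while the proteoglycan VCAN fell by 1.56; of 34 extracellular matrix genes 21 were higher and 8 lower, with 21 and 9 over the list alone. Of 23 cholesterol synthesis genes 14 were higher and 2 lower (median 0.57), with the same counts over the list alone. None of the 12 list calls in LN18 held with an estimated correlation, where their adjusted p ran from 0.287 to 0.656. With library totals in place of TMM the median of all genes in LN18 moved to -0.11 on the log2 scale, smaller in size than these list medians, and no median of a called list changed sign.

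In T98G resistant cells were likewise set against sensitive cells of that line. The sulfatase SULF1 rose from 1 read over the 2 sensitive libraries to 20.1 ± 2.82 CPM, a ratio of 746 (95% interval 133 to 29490.3). The fatty acid carrier FABP4, with 0 reads in sensitive cells, was at least 106-fold higher, and CHRDL1, also raised in LN18, went from 0.351 ± 0.189 to 190.3 ± 0.542 CPM (log2 9.06 ± 0.16, adjusted p = 4.73e-28, edgeR). The teneurin TENM1 rose by 8.05 on the log2 scale. The GDNF receptor GFRA1 fell from 85.3 ± 5.71 to 0.182 ± 0.038 CPM, the ligand TNFSF18 by 6.89 and the sterol transporter ABCG1 by 6.86. edgeR called 11118 genes, 5554 higher and 5564 lower, with 4665 changed at least 2-fold and 5305 past the 1.5-fold test.

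DR5 fell in T98G, where DR4 was near absence. TNFRSF10B went from 304 ± 2.82 to 100.3 ± 1.58 CPM (log2 -1.60 ± 0.067, adjusted p = 3.25e-19, edgeR), whereas TNFRSF10A had 1 read in sensitive and 2 in resistant libraries. The decoy TNFRSF10D had 4 and 1 reads. The caspase 8 inhibitor CFLAR rose from 20.3 ± 0.00848 to 38.2 ± 0.382 CPM (log2 0.91 ± 0.082), FAS by 0.76 and TNFRSF1A by 0.37, and the secreted decoy TNFRSF11B fell from 589 ± 5.48 to 83.5 ± 12.7 CPM. No call was made by edgeR for FADD (log2 0.03), CASP8 (0.16), CASP10 (-0.67), RIPK1 (0.14), TRADD (0.20), TNFSF10 (-0.30) or TNFRSF10C (-0.01). With library totals CASP8 and RIPK1 were called higher (adjusted p = 0.0241 and 0.0131; 0.0241 to 0.687 and 0.0131 to 0.407 over every alternative with a test of any change). Of 14 members 3 were higher and 2 lower, over all genes and over the list alone.

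Several mediators of mitochondrial death fell in resistant T98G cells: CYCS by 1.49 ± 0.066 on the log2 scale, BID by 1.52 ± 0.084 and the BH3-only gene PMAIP1 by 1.77 ± 0.093. Among inhibitors BIRC3 was at 87.3 ± 12.9 against 891 ± 96.6 CPM, PEA15 was lower by 1.19 and BCL2L1 by 0.79, while BIRC5 rose by 1.60. BIRC5 is counted in the G2/M list too. Of 19 pro-apoptotic genes and caspases 4 were higher and 9 lower (5 and 9 adjusted over the list alone), and of 14 anti-apoptotic genes 4 and 6, over all genes and over the list alone.

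NF-kB targets were lower in resistant T98G cells too. ICAM1 went from 79.4 ± 5.86 to 2.46 ± 0.165 CPM (log2 -5.01 ± 0.13, adjusted p = 2.99e-24, edgeR), and the NF-kB subunit genes NFKB2 and RELB fell by 2.1 and 2.86 on the log2 scale. The list had 22 of 31 members lower and 1 higher, over all genes and over the list alone, at a median of -2.19 (camera adjusted p = 5.64e-12, 0.287 with an estimated correlation). The interferon genes IRF1 and IFIH1 fell by 2.68 and 1.59; their list had 21 of 36 members lower and 5 higher (24 and 6 adjusted over the list alone). Genes of the amino acid response fell: ASNS went from 739 ± 6.0 to 49.7 ± 1.18 CPM, ATF3 from 239 ± 5.34 to 7.31 ± 1.19 CPM and PSAT1 fell by 2.6. The list of ATF4 and unfolded protein response genes had 29 of 30 members lower and 1 higher, over all genes and over the list alone, at a median of -1.76, and its call held with an estimated correlation (camera adjusted p = 2.81e-20 and 0.0255). Of 25 NRF2 and glutathione genes 20 were lower and 0 higher, over all genes and the list alone, with TXNRD1 lower by 1.62.

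Mitotic genes were higher in resistant T98G cells. KIF20A rose from 11.9 ± 0.807 to 288 ± 11.7 CPM (log2 4.59 ± 0.10, adjusted p = 9.14e-26, edgeR) and PLK1 by 2.85 on the log2 scale. Of 32 G2/M genes 30 were higher and 0 lower (32 and 0 adjusted over the list alone) at a median of 1.86, and of 32 G1/S genes 24 were higher and 4 lower, over all genes and the list alone, MCM5 by 1.22. FN1 rose from 1679 ± 55.9 to 7294 ± 299.6 CPM, and VIM, TAGLN, TNC and COL1A2 by 1.88, 3.46, 3.56 and 1.81. Of 34 extracellular matrix genes 19 were higher and 11 lower, and of 31 mesenchymal genes 14 and 12, over all genes and the list alone. The matrix list had a camera adjusted p of 0.0395 (0.739 with an estimated correlation) and was not called with the replicate block (0.132) or without sensitive replicate 1 (0.0606). The neuronal gene MAP2 and the oligodendrocyte factor OLIG2 fell by 5.79 and 4.55, the efflux pump ABCG2 by 2.98 and VEGFA by 2.06. Apart from the ATF4 list, the other 9 list calls in T98G did not hold with an estimated correlation (adjusted p 0.287 to 0.868).

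**Figure D2:**
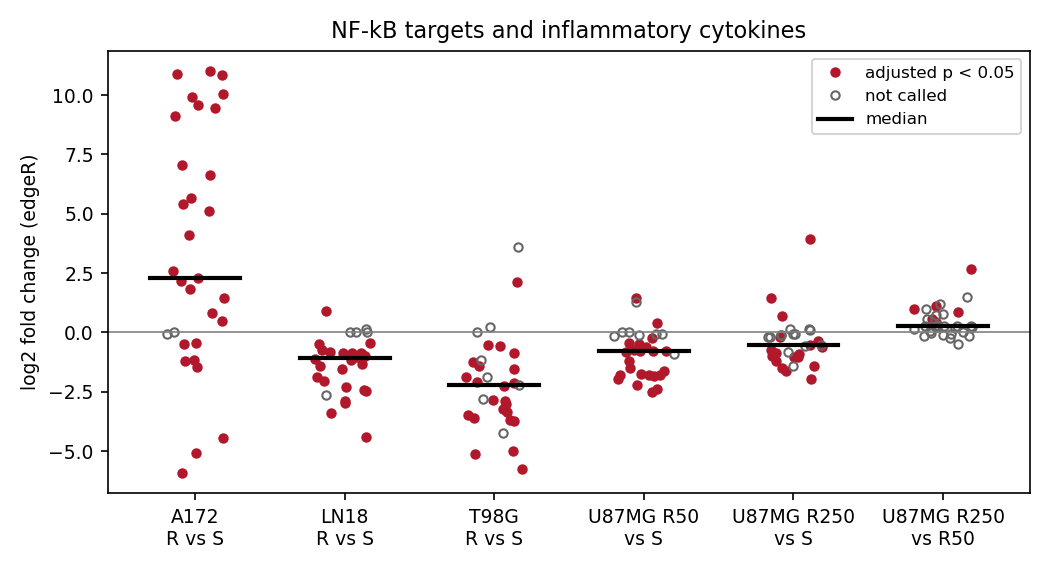
Log2 fold change (edgeR, vertical axis) of the 31 measured NF-kB targets and cytokines in 6 comparisons (horizontal axis), filled where the adjusted p was under 0.05, with the median as a bar. The median was -1.09 in LN18, -2.19 in T98G, -0.79 in U87MG R50 and -0.54 in R250, and 2.28 for the libraries labelled A172 resistant.

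U87MG R50 cells were compared with the sensitive U87MG cells. The secreted WISP2 rose from 0.233 ± 0.0988 to 7.77 ± 0.607 CPM (log2 5.05 ± 0.28, adjusted p = 5.29e-15, edgeR), the nitric oxide synthase NOS1 from 4.15 ± 0.127 to 55.8 ± 9.68 CPM, and IGFBP2, which binds insulin-like growth factors, by 3.61 on the log2 scale. PLEKHA6, THY1 and the death-associated kinase DAPK1 rose by 3.44, 3.39 and 3.17. The matrix gene EMILIN2 fell from 6.56 ± 0.368 to 0.342 ± 0.00528 CPM, the cytokine IL36B from 36.7 ± 0.2 to 3.55 ± 0.142 CPM, and the protease inhibitor PI3 and collagenase MMP1 by 2.87 and 2.82. edgeR called 3830 genes, 1924 higher and 1906 lower, 843 of them at least 2-fold; 646 passed the 1.5-fold test. The count was 2348 without sensitive replicate 2, 2335 without R50 replicate 1 and 2553 without R50 replicate 2.

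Among the TRAIL receptors the decoy TNFRSF10D fell most in R50 cells, from 88.0 ± 2.18 to 35.7 ± 0.517 CPM (log2 -1.30 ± 0.078, adjusted p = 4.81e-14, edgeR), and DR5 (TNFRSF10B) fell by 0.36 ± 0.064 on the log2 scale. DR4 (TNFRSF10A) was at 0.92 ± 0.0512 CPM in sensitive and 0.462 ± 0.0484 CPM in R50 cells (adjusted p = 0.015), and its call was lost without sensitive replicate 2 (0.11), R50 replicate 1 (0.056) or R50 replicate 2 (0.121; 0.00952 to 0.121 over every alternative with a test of any change). The other 11 measured members, among them FADD (log2 0.08), CASP8 (-0.17), CFLAR (-0.18), RIPK1 (-0.02), FAS (-0.11), CASP10 (0.34), TRADD (0.19), TNFRSF1A (0.03), TNFRSF11B (0.07), TNFRSF10C (0.03) and TNFSF10 (0.40), were not called by edgeR (adjusted over the list alone, 0 higher and 4 lower). Some alternatives called CFLAR, DESeq2 among them (adjusted p = 0.0291; 0.00615 to 0.355 over every alternative with a test of any change), and the fit to the 4 libraries alone called CASP8 (0.0252; 0.0252 to 0.489). BIRC2 fell by 0.51 ± 0.088 and BIRC3 by 1.5, while the BH3-only gene BCL2L11 rose by 0.73 and FAIM2, an inhibitor of FAS signalling, by 0.90. Of 19 pro-apoptotic genes and caspases 3 were higher and 5 lower (4 and 5 adjusted over the list alone), and of 14 anti-apoptotic genes 3 and 3 (3 and 4).

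NF-kB targets were lower in R50 cells as well. CSF3 went from 275 ± 15.1 to 48.5 ± 2.64 CPM (log2 -2.50 ± 0.10, adjusted p = 4.02e-13, edgeR), IL1B from 171.3 ± 1.18 to 43.7 ± 5.75 CPM, and LIF fell by 1.22 on the log2 scale, whereas TNFAIP2 rose by 1.45. The list had 21 of 31 members lower and 2 higher, over all genes and the list alone, at a median of -0.79 (camera adjusted p = 1.71e-13, 0.287 with an estimated correlation). The glycoprotein CHI3L1 rose from 82.3 ± 2.07 to 580.01 ± 57.9 CPM, COL1A1 and HMOX1 by 0.77 and 1.07, and VIM and MCM10 fell by 0.62 and 0.83. The other list calls were small: G1/S genes had a median of -0.10 with 6 of 32 lower and 0 higher, over all genes and the list alone, and oxidative phosphorylation a median of 0.15 with 9 of 32 higher, ATP5A1 by 0.49, and 2 lower (11 and 2 adjusted over the list alone). Neither held with an estimated correlation (adjusted p = 0.812 and 0.665).

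In U87MG R250 cells the leading genes were largely those of R50. IGFBP2 went from 2.06 ± 0.15 to 52.5 ± 0.634 CPM (log2 4.67 ± 0.14, adjusted p = 1.17e-19, edgeR), PLEKHA6 rose by 4.01 on the log2 scale, NOS1 by 3.43 and SERINC2 by 3.12. EMILIN2 fell by 4.72, IL36B by 3.38, the chromatin gene BCL7A by 3.46, and SLFN11, which blocks stressed replication forks, went from 14.5 ± 0.404 to 1.61 ± 0.00217 CPM. edgeR called 4769 genes, 2348 higher and 2421 lower, 1065 of them at least 2-fold, and 939 passed the 1.5-fold test. The count was 2963 without sensitive replicate 2, 3153 without R250 replicate 1, 3098 without R250 replicate 2, and 7233 in a fit to the 4 libraries alone.

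TNFRSF10D fell in R250 cells to 34.4 ± 0.442 CPM (log2 -1.36 ± 0.078, adjusted p = 1.47e-14, edgeR). Small changes were called for TNFRSF10B (log2 -0.24), CASP10 (0.50) and TRADD (0.31), and each lost its call without single libraries. TRADD also lost its call with DESeq2 (adjusted p = 0.0517) and with edgeR after thinning to equal depth (0.0576). Without sensitive replicate 2 the adjusted p was 0.0617 for TNFRSF10B, 0.164 for CASP10 and 0.333 for TRADD. Without R250 replicate 1 it was 0.0512 for TNFRSF10B and 0.0658 for TRADD, and without R250 replicate 2 it was 0.0682, 0.0872 and 0.212 for the same 3 genes. Over every alternative with a test of any change, the adjusted p ran from 2.91e-06 to 0.0682 for TNFRSF10B, 6.89e-04 to 0.164 for CASP10 and 0.00118 to 0.333 for TRADD. FADD (log2 0.23) was called only without sensitive replicate 1 (adjusted p = 0.0335). CASP8 (-0.21), CFLAR (-0.17), RIPK1 (0.03), FAS (0.00), TNFRSF10A (-0.57), TNFRSF10C (0.11), TNFRSF11B (-0.43), TNFRSF1A (-0.11) and TNFSF10 (-0.62) were not called by edgeR, which makes 2 of 14 higher and 2 lower (2 and 3 adjusted over the list alone). Some alternatives called CFLAR, DESeq2 among them (adjusted p = 0.0338), CASP8, TNFRSF11B and TNFRSF1A. Over the alternatives the adjusted p ran from 0.00178 to 0.339 for CFLAR, 0.00373 to 0.351 for CASP8, 0.0169 to 0.602 for TNFRSF11B, 0.0246 to 0.621 for TNFRSF1A and 0.0335 to 0.982 for FADD.

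BIRC3 fell in R250 cells to 2.12 ± 0.492 CPM (log2 -1.63 ± 0.27, adjusted p = 7.67e-04, edgeR), BIRC2 by 0.60 and BID by 0.47 on the log2 scale, and BCL2L11 and FAIM2 rose by 0.51 and 1.16. Of 19 pro-apoptotic genes and caspases 4 were higher and 5 lower (6 and 6 adjusted over the list alone), and of 14 anti-apoptotic genes 4 and 4 (4 and 5). CSF3, IL1B, LIF and NFKB1 fell by 1.95, 0.87, 0.76 and 0.90 and TNFAIP2 rose by 1.44; the NF-kB list had 15 of 31 members lower and 3 higher (17 and 3 adjusted over the list alone) at a median of -0.54 (camera adjusted p = 3.71e-05, 0.600 with an estimated correlation). Cyclin A2 (CCNA2) and CENPE fell by 0.87 and 0.85, with 11 of 32 G2/M genes lower and 1 higher (12 and 1 over the list alone) at a median of -0.16 (camera adjusted p = 0.00502, 0.768 with an estimated correlation). The p53 targets BTG2, ZMAT3 and EDA2R rose by 1.09, 0.50 and 0.57, and 11 of 27 genes of that list were higher and 2 lower, over all genes and the list alone, at a median of 0.13 (camera adjusted p = 0.00301, 0.287 with an estimated correlation). HMOX1 rose to 2125 ± 60.2 CPM from 593 ± 32.1 CPM.

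R250 was set against R50 to see whether the 2 resistant U87MG derivatives differ. The channel subunit CACNG8 was higher in R250 at 13.3 ± 0.0158 against 4.51 ± 0.425 CPM (log2 1.56 ± 0.11, adjusted p = 1.71e-10, edgeR), as were MMP15 by 1.52, IGFBP2 by 1.06, the matrix gene FBLN1 by 2.67, the protease inhibitor TIMP1 by 0.59 and HMOX1 by 0.78 on the log2 scale. Lower in R250 were ZBTB7C by 1.78, ACTL8 by 1.56, ADD2 by 1.37, THY1 by 1.36 and COL1A1 by 0.40. The NF-kB list was less depressed in R250: IL1B was at 93.5 ± 1.79 against 43.7 ± 5.75 CPM, LIF was higher by 0.46, and 6 of 31 members were higher and 0 lower (13 and 0 adjusted over the list alone) at a median of 0.26 (camera adjusted p = 1.76e-12, 0.287 with an estimated correlation). None of the 14 TRAIL list genes was called by edgeR, with TNFRSF10D at log2 -0.05 and TNFRSF10B at 0.12; 1 had an unadjusted p under 0.05 and DESeq2 called 0, while the fit to the 4 libraries alone called TNFRSF10B (adjusted p = 0.0111; 0.0111 to 1 over every alternative with a test of any change). In that fit HMOX1 was not called (adjusted p = 0.0532; 9.54e-25 to 0.0532 over every alternative with a test of any change). edgeR called 368 genes, 145 higher and 223 lower, 94 of them at least 2-fold, and 36 passed the 1.5-fold test. The count moved with each library left out: 150 without R50 replicate 1, 198 without R50 replicate 2, 149 without R250 replicate 1 and 149 without R250 replicate 2.

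**Figure D3:**
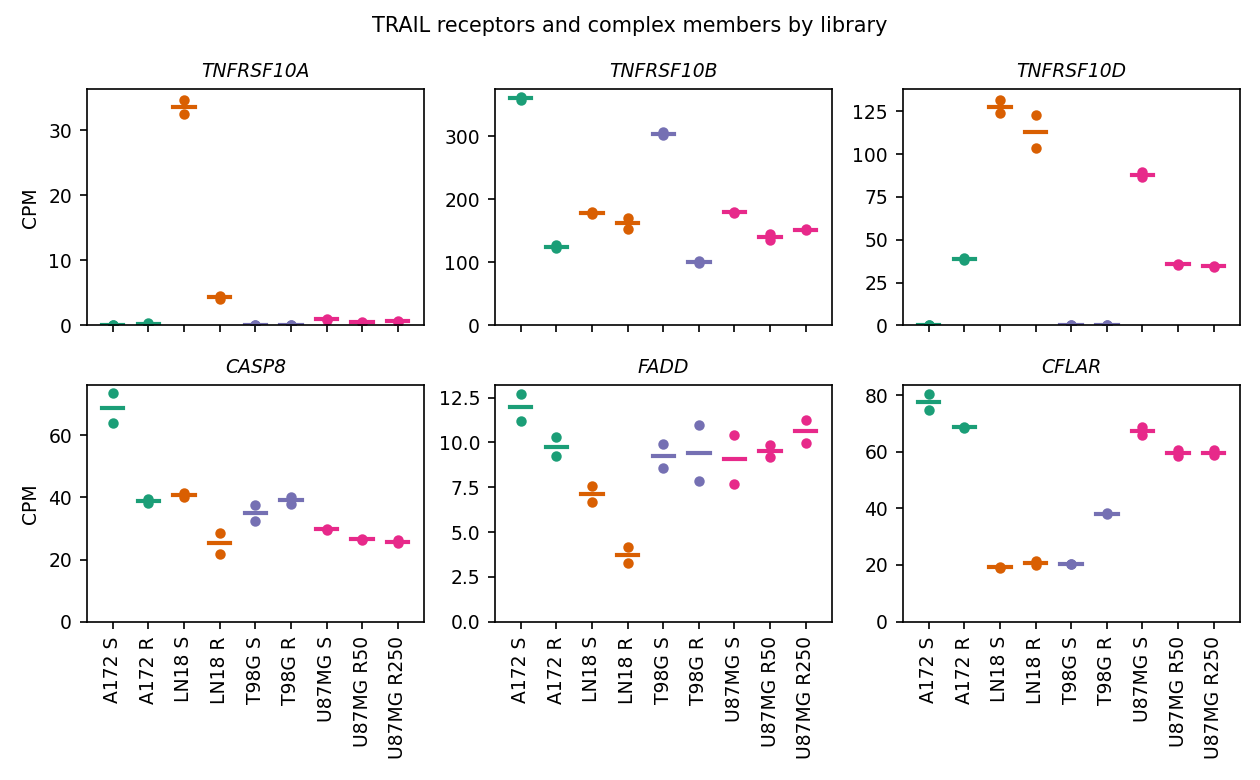
Level (CPM, vertical axis) of 6 genes of the TRAIL list in each library, by group on the horizontal axis; points are single libraries, bars the mean of 2, colours the cell lines. TNFRSF10B fell from 304 ± 2.82 to 100.3 ± 1.58 CPM in T98G and TNFRSF10A from 33.5 ± 1.54 to 4.32 ± 0.317 CPM in LN18.

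The libraries labelled A172 resistant differed from sensitive A172 cells at more genes than any other pair of groups compared. The caveolar gene PRKCDBP, with 0 reads in sensitive A172, was at 63.2 ± 0.989 CPM, at least 848-fold higher, and BTBD6 and the convertase PCSK2 were at least 625 and 620.03-fold higher. The neural stem cell gene MSI1 was at least 122-fold lower, and the matrix linker HAPLN1 went from 65.5 ± 4.4 CPM to 1 read, a ratio of 2429 (95% interval 436 to 95988). edgeR called 13899 of 19784 genes, 6989 higher and 6910 lower, 7734 of them at least 2-fold; 8887 passed the 1.5-fold test. These libraries resemble U87MG, so a difference between lines and a change with resistance cannot be told apart here.

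In that comparison TNFRSF10B fell from 359 ± 2.71 to 125 ± 3.94 CPM (log2 -1.52 ± 0.066, adjusted p = 2.04e-19, edgeR), TNFSF10, RIPK1 and CASP8 fell by 2.02, 1.25 and 0.82 on the log2 scale, and TNFRSF10D rose from 1 read to 38.7 ± 0.457 CPM, a ratio of 1561 (95% interval 279.7 to 61704). Of the 14 members of the TRAIL list 7 were higher and 6 lower, over all genes and the list alone. BCL2L11 fell by 2.75. IL1B rose from 1.89 ± 0.0138 to 3547 ± 528 CPM, ICAM1 by 9.46, TNC by 8.82 and TGFBI by 8.05, while of 34 extracellular matrix genes 14 were higher and 19 lower (the same counts over the list alone). The collagens COL4A1 and COL4A2 fell by 7.07 and 5.53, the keratins KRT8 and KRT18 by 4.95 and 5.35, GPM6A by 7.18, and HOXB9 and HOXB8 by 7.63 and 7.06. Of 29 HOX genes 23 were lower and 3 higher, over all genes and the list alone (median -2.80; camera adjusted p = 7.45e-08, 0.0255 with an estimated correlation); leaving out the member with 0 reads in both groups gave a median of -3.42. CA12 and HK2 rose by 6.52 and 5.30, with 27 of 31 hypoxia and glycolysis genes higher and 3 lower (the same counts over the list alone), and RPL11 rose by 1.61, while MX2 and HMGCS1 fell by 4.94 and 2.33. The other 9 list calls did not hold with an estimated correlation (adjusted p 0.287 to 0.706).

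**Figure D4:**
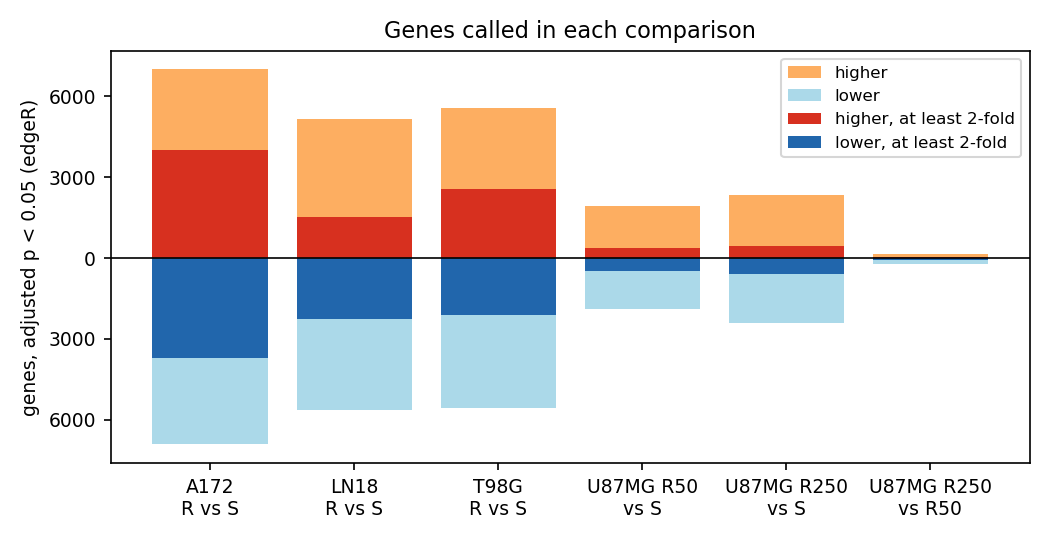
Number of genes called by edgeR in each of 6 comparisons (horizontal axis), higher above and lower below 0 (vertical axis), with the part that changed at least 2-fold in darker colours. Calls ran from 368 for R250 with R50 to 13899 for the libraries labelled A172 resistant.

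The shared change asked which genes moved the same way with resistance in all 4 lines. DAAM2, a formin of WNT signalling, was higher in each: by 5.36 in the libraries labelled A172 resistant, 2.82 in LN18, 3.8 in T98G, 3.25 in R50 and 3.43 in R250 on the log2 scale, with a shared estimate of 3.81 ± 0.495 over 8 sums. The growth factor FGF2 was lower in each, by 1.12, 1.34, 1.71, 1.24 and 1.16 in the same order, as was the cystine carrier SLC7A11, by 2.63, 1.13, 2.37, 1.06 and 1.29. The chemokine CXCL14, the phosphatase ACP5, the coactivator PPARGC1A, the ligase FBXO32 and the kinase PAK4 had shared estimates of 4.24, 1.75, 1.63, 0.87 and 0.94, and CDYL2 and KBTBD11 of -1.78 and -3.54. KBTBD11 fell by 3.94, 1.34, 4.56, 4.12 and 4.34 and CDYL2 by 2.79, 1.30, 1.58, 1.5 and 1.56 in that order. CXCL14 was at least 32.6-fold higher in the libraries labelled A172 resistant, higher by 4.68 on the log2 scale in LN18, 2.41 in R50 and 2.83 in R250, and in T98G went from 3 to 35 reads, a ratio of 11.2 (95% interval 3.53 to 56.9). By edgeR 0 of 19784 genes were called: 895 had an unadjusted p under 0.05 where 989 are due by chance, and the smallest adjusted p was 0.839. DESeq2 called 74 genes (1671 with an unadjusted p under 0.05), among them DAAM2 (adjusted p = 5.54e-11; 5.54e-11 to 0.934 over every alternative), FGF2 (3.16e-06; 7.6e-07 to 0.934) and SLC7A11 (0.00344; 5.78e-05 to 0.934). Without A172, edgeR again called 0 genes, with 1095 at an unadjusted p under 0.05 and DAAM2 first (log2 3.34, adjusted p = 0.167). As a fit to single libraries edgeR called 3894 genes, since it takes libraries of the same line as independent. The replicate block, which takes them so too, called DAAM2 (edgeR adjusted p = 0.00802), FGF2 (0.00366) and SLC7A11 (0.026). With no filter on low counts edgeR called DAAM2 (adjusted p = 0.00665).

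**Figure D5:**
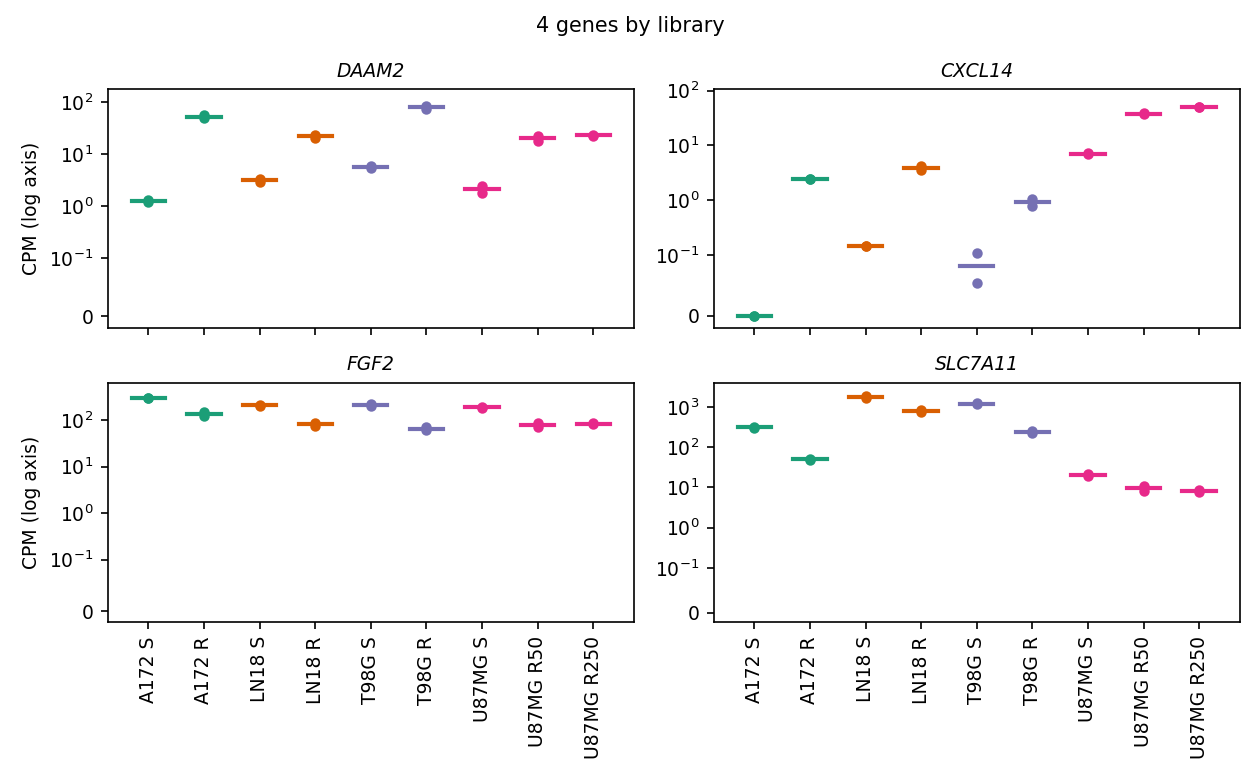
Level (CPM, vertical log axis, linear under 0.1) of DAAM2, CXCL14, FGF2 and SLC7A11 in each library, by group on the horizontal axis; points are single libraries, bars the mean of 2, colours the cell lines. In U87MG, DAAM2 was at 2.13 ± 0.446 CPM in sensitive, 20.4 ± 2.99 CPM in R50 and 23.1 ± 1.31 CPM in R250 cells.

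Most genes did not change alike in the 4 lines: edgeR called 16300 of 19784 genes (82.4%) for a difference of the resistance change between lines, and 13229 without the A172 libraries. Genes called the same way in all 5 comparisons with sensitive cells numbered 273, 123 higher and 150 lower, against 12.4 if calls fell independently. Without sensitive U87MG replicate 2 the number was 166. R50 and R250 come from the same line and share their controls, which lifts the number of 273. The 12.4 takes R50 and R250 as independent of each other, so it is too low. The size of the excess cannot be read from it. Past 2-fold in all 5 were 13 genes. In LN18, T98G, R50 and R250 together, 32 genes were past 2-fold the same way; of these IL8, IL6, HES1 and MEST were picked after their values were seen. IL8 fell by 3.41, 5.11, 2.40 and 1.40 and IL6 by 1.32, 3.68, 1.78 and 1.02, but both rose in the libraries labelled A172 resistant (10.03 and 6.62). The NOTCH target HES1 fell by 2.67 in the libraries labelled A172 resistant, 1.53 in LN18, 1.13 in T98G, 3.78 in R50 and 3.08 in R250, and the imprinted MEST rose by 7.62, 1.43, 1.03, 1.92 and 1.76.

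LN18 and T98G, the 2 lines other than U87MG whose identity held, shared 2040 genes higher in both against 1447 due by chance and 2299 lower in both against 1587 (Fisher's exact test, adjusted p = 1.63e-96 and 2.84e-131). That test takes genes as independent, which they are not, and its p-values do not measure whether the overlap would recur in other lines. Log2 fold changes of the 2 lines correlated across genes at r = 0.14. In opposite directions 2648 genes were called, against 3034 if calls fell independently. U87MG was less like either line. T98G correlated at r = 0.017 with R50 and -0.011 with R250, with 1225 and 1509 opposite calls against 1076 and 1340. LN18 correlated at 0.048 with R50 and 0.025 with R250, with 1002 and 1325 opposite calls against 1045 and 1301. Calls in the same direction also exceeded the number due by chance in each of these pairs. R50 and R250 were called alike for 1538 higher and 1609 lower genes and in opposite directions for 12, with r = 0.754 across genes. Part of that likeness comes from the shared controls: simulated groups with no change gave a mean r of 0.518 against 0.73 observed in a fit to the 6 U87MG libraries, and at most 6 genes called higher in both against 2529.

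Across the 26 lists and 7 tests each, camera called 55 of 182, and 2 held with an estimated correlation, the HOX genes in A172 and the ATF4 list in T98G. fry called 79 of the 182 tests for a move one way and 138 for change in either direction. For every camera call the median, the mean and the test had the same sign. In the shared change camera called 9 lists, among them NF-kB targets at a median of -0.78, interferon-stimulated genes at -0.87, the ATF4 list at -0.66 and neural stem and proneural genes at -0.91 on the lower side, and G2/M genes at 0.72, hypoxia and glycolysis at 0.63 and oxidative phosphorylation at 0.33 on the higher side. Without the A172 libraries hypoxia and glycolysis was not called (median 0.13, adjusted p = 0.0652; 2.8e-06 to 0.706 over the alternatives with camera), and the medians were -1.45 for NF-kB, -0.42 for interferon-stimulated, -0.69 for ATF4, -0.69 for neural stem, 0.84 for G2/M and 0.21 for oxidative phosphorylation genes. The adjusted p with an estimated correlation was 0.600 or more. A list call in the shared change is for an average over the lines, and not every line moved that way. The NF-kB median was 2.28 in the libraries labelled A172 resistant, and the G2/M median was -0.16 in R250. Neural stem genes had medians of 0.0055 in R50 and -0.013 in R250. The ATF4 list was lower in A172 (-0.58), LN18 (-0.48) and T98G (-1.76). The lists of pro-apoptotic genes, anti-apoptotic genes, death receptor glycosylation, antigen presentation, astrocyte genes, immune cells, endothelium and neurons were not called by camera in any of the 7 tests.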

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

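The tests of the explanations below were chosen after the results were seen; the test of a difference between the lines was planned. The 6 gene lists and 77 named genes listed here were picked because the change between resistant and sensitive cells went opposite ways in different cell lines. Among all genes this is common. Of 19784 genes, 16300 (82.4%) were called for a difference between the lines, and 2648 were called in opposite directions in LN18 and T98G.

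For each list the difference is between the comparisons with the smallest p for a rise and for a fall. NF-kB targets and cytokines had a median log2 fold change of 2.28 in the libraries labelled A172 resistant and -0.79 in U87MG R50, a difference of 3.06, and were also lower in T98G (-2.19), LN18 (-1.09) and R250 (-0.54). G2/M genes were higher in T98G (1.86) and lower in U87MG R250 (-0.16), a difference of 2.02, and G1/S genes higher in T98G (0.49) and lower in LN18 (-0.96), a difference of 1.45. Cholesterol synthesis was higher in LN18 (0.57) and lower in A172 (-0.98), a difference of 1.54, and also higher in T98G (0.60). NRF2 and glutathione genes (0.43 and -0.89, a difference of 1.32) and cytosolic ribosomal proteins (0.83 and -0.25, a difference of 1.08) were higher in LN18 and lower in T98G; the ribosomal list was also higher in A172 (0.59). It was not called in T98G with the A172 libraries left out (camera adjusted p = 0.105) or without sensitive replicate 2 (0.0614) or resistant replicate 1 (0.129); over the alternatives with camera the adjusted p ran from 0.00795 to 0.868, and with fry it was 0.00535. The lists were picked for calls in opposite directions, so a camera test of the difference between the same 2 comparisons is no separate evidence; each list had an adjusted p of 3.75e-08 or less; with an estimated correlation the unadjusted p was 0.00723 for G2/M, 0.00802 for NRF2, 0.0282 for ribosomal and 0.0585, 0.0727 and 0.095 for the G1/S, NF-kB and cholesterol lists.

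Among the 139 gene symbols named, 77 were called higher in a line and lower in another, 44 of them also with A172 left aside. Their edgeR adjusted p for any difference between the 4 lines was 3.67e-06 or less. A value under 0.05 in that test was required for entry, so it is no separate evidence. The values are the gap in log2 fold change between the comparison with the highest and the one with the lowest called value, and A172 stands for the libraries labelled A172 resistant. Higher in A172 and lower in LN18 were CSF3 15.45, IL1B 13.28, HMOX1 5.06, TNFRSF10A at least 4.81, XRCC2 4.15, TNFAIP3 3.69, TNFRSF10C 3.59, ZBTB7C 3.53, CACNG8 2.55, CASP10 1.70 and FAS 1.44. Higher in A172 and lower in T98G were IL8 15.14, ICAM1 14.47, IL6 10.30, MAP2 8.68, TGFBI 8.48, CA12 7.03, PLEKHA6 6.60, HK2 5.86, ABCG2 5.69, CHI3L1 5.31, NDRG1 4.89, VCAN 4.35, BIRC3 3.84, TNFRSF11B 3.70, LIF 3.54, VEGFA 2.87, PMAIP1 2.30, BID 2.18 and CYCS 2.02. Higher in A172 and lower in R250 were IL36B 14.38, PCSK2 at least 12.16, TNFRSF10D 11.96, VIM 2.76 and BIRC2 1.29. Higher in A172 and lower in R50 were PI3 10.34, MMP1 9.07 and TIMP1 4.54. Higher in LN18 and lower in T98G were NCAM1 8.61 and BCL2L1 1.46. Higher in LN18 and lower in A172 were COL4A1 8.23, COL4A2 6.11, KRT8 5.27, SPARC 4.79, HMGCS1 3.34 and BAK1 2.54. Higher in LN18 and lower in R250 was CADM1 6.44. Higher in T98G and lower in A172 were SULF1 17.35, HAPLN1 17.18, TENM1 9.40, KRT18 5.76, TAGLN 5.20, BCL7A 4.80, MMP15 3.86, COL1A2 2.80, CFLAR 1.08 and TNFRSF1A 1.06. Higher in T98G and lower in R250 were KIF20A 4.91, PLK1 3.14, CCNA2 3.05 and CENPE 2.84. Higher in T98G and lower in LN18 were UHRF1 2.56, MCM5 2.12, MCM3 2.11 and MCM10 1.93. Higher in R50 and lower in A172 were DAPK1 9.79, THY1 8.70, ADD2 7.49 and BCL2L11 3.49. Higher in R50 and lower in LN18 was TNFAIP2 2.59. Higher in R250 and lower in A172 were IGFBP2 10.43, FBLN1 4.81 and SERINC2 4.16. Higher in R250 and lower in LN18 were HRK 4.67 and BTG2 1.72. Higher in R250 and lower in T98G were ASNS 4.23 and PEA15 1.5. HAPLN1, PCSK2 and TNFRSF10A have a group with 0 reads, so their gaps use a bound, and SULF1, HAPLN1, IL36B, TNFRSF10D and NCAM1 rest on 1 to 3 reads in a group, where the ratio of reads was used. FAS was not called in LN18 without sensitive replicate 1 (adjusted p = 0.0502) or resistant replicate 2 (0.107), nor CASP10 without sensitive replicate 1 (0.213), resistant replicate 1 (0.098) or resistant replicate 2 (0.0782), with DESeq2 (0.089) or in the fit to the libraries of the comparison alone (0.0537).

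Many of these gaps rest on the libraries labelled A172 resistant, which resemble U87MG cells. A swap of labels with another resistant group would leave A172-like libraries in that group. Of the 16 libraries of other groups, 0 were closest to a line other than their own. The 8 sensitive libraries among them define the lines, and each was compared with the other library of its own group. They would be in place in any case, so a swap that involves a whole sensitive group cannot be seen this way. U87MG-like cells in place of A172 cells would carry the genes restricted to U87MG, and 96.3% of these were seen. Of 20 genes restricted to LN18, however, 6 reached 1 CPM in the libraries labelled A172 resistant, against 0 in R50 and 0 in R250. Mitochondrially encoded transcripts, though, summed to 93995 CPM against 16259 CPM in sensitive U87MG and 85112 CPM in sensitive A172 cells. The U87MG libraries also stood apart in depth, at 37.1 to 44.6 M reads against 19.1 to 20.3 M in all other libraries. Line and library set cannot be told apart by these sums. A change of expression within A172 cells might leave part of the genes restricted to A172 in place, but 0% of these were seen. These genes were picked as high in sensitive A172 cells, and such a change could itself have lowered them. Their absence therefore cannot decide the question. Expression alone cannot settle the identity, and no genotype was tested.

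For the shared change, the 8 sums can be split into 2 groups of 4 in 35 ways, of which 3 could not be fitted beside the cell line. With edgeR the real split gave 0 calls (895 genes at an unadjusted p under 0.05, 74 called by DESeq2), a number that 32 of the 32 fitted splits reach by construction, and the highest of the others gave 2. The number of calls therefore says nothing about chance. By genes at an unadjusted p under 0.05, 11 of the 32 had at least 895, the highest of the others having 3040, so chance is not excluded. The splits above the real one part 2 of the 4 lines; of the 8 that part all 4, too few for a share under 0.05, only the real one had as many, the highest of the others having 680 (1 of 8).

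The fall of the NF-kB list in LN18, T98G, R50 and R250 was weighed against the processing. Scaling would have to bring the list to the median of all genes, but over the 3 scalings its weakest median was -0.54 (in R250), and with every library thinned to equal depth it was -0.43, so neither accounts for it. A share of dividing cells that changed alike in the 4 comparisons would move G2/M genes alike, but their median was -0.16 in R250 and 1.86 in T98G. This argues only against an effect common to the 4 comparisons. In LN18 (median 1.09) and T98G the G2/M genes rose where the NF-kB list fell, so a part played by dividing cells there is not excluded. A change that comes with resistance remains as an explanation. Separate culture or selection of the resistant cells was not tested and may have the same result.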

How the results depend on the processing

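Thinning to equal depth and leaving out the A172 libraries were chosen after seeing the data, as was leaving out libraries for the shared change, the overlap, the lists and the identity. The counts of called genes for A172, LN18, T98G, R50, R250 and the difference between the lines were within 1.5 times the reported ones with DESeq2 size factors, library totals, no filter, the stricter filter, the DESeq2 test, the replicate block and thinning, and, except for A172, where it cannot be run, with the A172 libraries left out. So were those for R250 with R50 apart from the block and thinning. The identity count was 8 with Spearman correlation, without TMM and with a filter of 10 CPM. The cause of the changes below was not tested except where it is stated.

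Testing against a fold of 1.5, a stricter question by construction, gave 8887 genes in A172, 4071 in LN18, 5305 in T98G, 646 in R50, 939 in R250 and 36 for R250 with R50. A fit to the libraries of a comparison alone, which sets aside the spread of the other groups, gave 7233 in R250 and 2192 for R250 with R50. Thinning, which leaves fewer reads, gave 199 for R250 with R50 and the replicate block 612, though the replicate numbers do not pair the samples (correlation of the differences from group means -0.018 to 0.054).

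The shared change was reported as 0 genes with edgeR (895 at an unadjusted p under 0.05). Leaving out the filter gave 2, the replicate block 104 and DESeq2 74. Single libraries gave 3894 and single libraries without A172 3985. Both fits to single libraries and the replicate block count libraries of a line as independent. Size factors, library totals, the stricter filter, R50 or R250 alone and leaving out each line gave 0. The overlap of calls in all 5 comparisons was 13 with a 2-fold minimum and 536 with the A172 libraries left out, where 4 comparisons remain. Of the 55 list calls 2 held with an estimated correlation.

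Leaving out each library, which leaves a group with 1, gave 13124 to 13248 genes in A172, 9216 to 10345 in LN18, 9933 to 10014 in T98G, 2335 to 2846 in R50, 2963 to 3768 in R250, 149 to 198 for R250 with R50, 16097 to 16475 for the difference between the lines, 0 to 0 for the shared change, 166 to 337 for the overlap and 52 to 57 list calls. The R50 count was 2348 without sensitive replicate 2, 2335 without R50 replicate 1 and 2553 without R50 replicate 2, and the R250 count 2963, 3153 and 3098 without sensitive replicate 2, R250 replicate 1 and R250 replicate 2. For R250 with R50 it was 150 and 198 without R50 replicates 1 and 2 and 149 without either R250 replicate, and the overlap was 166 without sensitive U87MG replicate 2.

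Of 273 values of named genes in a comparison 226 were called, and under the alternatives 3811 of 3962 values kept their direction and side of the threshold, 53 lost a call, 70 gained one and 28 that were not called changed sign; 0 called values reversed. DESeq2 kept 224 of the 226 calls, thinning 225, the fit to single comparisons 224 and the fold of 1.5 194. Of the 55 list calls fry lost 17 and the replicate block 4, and leaving out a library lost 12 of 346. Depth and scaling set the floor: 3 reads are 0.162 CPM in the shallowest and 0.0648 CPM in the deepest library, and at most 0.164 CPM.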

Other observations

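The tests in this part were chosen after the patterns were seen in the calls, so each is a hypothesis tested on the data that raised it. Families were compared with all other tested genes by Fisher's exact test, adjusted over 24 tests, and members of a family are not independent.

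Zinc finger genes named ZNF were frequent among increases of at least 2-fold in U87MG: 44 of 517 in R50 (odds ratio 5.3, adjusted p = 5.87e-16) and 51 in R250 (5.06, 2.87e-17). Falls of that size were seen for 21 and 28 of the 517, and for 467 and 606 of all 19784 genes. Only increases were tested, so a one-way change of the family is not shown. Levels were low, with a median of 4.43 CPM for R50 and 4.64 CPM for R250 with sensitive cells. That ZNF genes may rise with resistance in every line was tested in LN18. There 19 were higher and 123 lower (odds ratio 0.453, adjusted p = 8.47e-04), so it can be excluded. The direction of the family median in R50, R250 and LN18 held with size factors and library totals.

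In resistant T98G cells 31 of 44 clustered protocadherins rose at least 2-fold and 0 fell that far (odds ratio 16.2, edgeR; median log2 1.85, the same with the 8 members without reads in a group at their bound). Reads of the exons that genes of the alpha and gamma clusters share could have carried this. The beta cluster, whose genes share no exons, had 12 of 17 genes higher and a median of 2.30. Reads of those shared exons are therefore not the sole cause. Reads shared between close relatives within a cluster cannot be separated in these counts and were not tested. Levels were low, with a median of 0.732 CPM over the 44 genes and 2.31 CPM in the beta cluster. Both medians of the change kept their sign in every scaling. What else could raise the clusters was not tested.

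Set against sensitive U87MG cells, the libraries labelled A172 resistant may share the change of the resistant U87MG cells. Over the 3147 genes called alike in R50 and R250, they moved the same way for 67.7 to 68.6% of genes, depending on which of the 2 sensitive libraries served as their control while the other served R50 and R250, against 52.0 to 57.4% for sensitive A172 and the LN18 and T98G groups. The genes were picked with both sensitive libraries, and no U87MG-like group without resistance is at hand to compare, so the hypothesis stays open; no p-value goes with this share. Mitochondrially encoded transcripts summed to 93995 CPM in these libraries and 85112 CPM in sensitive A172. The sums were 46123 and 43897 CPM in sensitive and resistant LN18, and 64213 and 77619 CPM in sensitive and resistant T98G. They were lowest, at 16259, 17752 and 18110.3 CPM, in sensitive U87MG, R50 and R250 cells. The U87MG libraries are also the deeper set, so line and library set cannot be told apart for these sums. Of 9 metallothioneins 8 were at least 2-fold higher than in sensitive A172 (adjusted p = 1.02e-04).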
